A study of Pseudotsuga menziesii with 75 samples.

How the data were processed

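RNA-seq of needles of the previous year was analysed from mature Douglas-fir (Pseudotsuga menziesii) trees sampled in 2010. Per the labels, the trees came from 2 provenances, Salmon Arm and Cameron Lake, and grew at 2 sites, Wiesloch and Schluchsee. Needles were taken in May (20 libraries), June (17), July (20) and September (18), which made 16 groups of 4 to 5 libraries. The 75 libraries came from 25 trees, identified here by provenance, site and replicate number. Salmon Arm had 7 trees at Wiesloch (19 libraries) and 6 at Schluchsee (18 libraries), and Cameron Lake had 5 at Wiesloch (19 libraries) and 7 at Schluchsee (19 libraries). Trees gave 4 libraries (11 trees), 3 (6 trees), 2 (5 trees) or 1 (3 trees). Each site was visited on a single day per month: Wiesloch on 12 May, 16 June, 14 July and 8 September, and Schluchsee on 27 May, 30 June, 28 July and 15 September. Month and day, and site and day, are therefore the same thing in these data. The labels gave a clock time for 62 libraries.

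The deposited matrix holds whole-number read counts for 59189 transcript contigs of a needle transcriptome assembly. CASAVA 1.7, Bowtie2 2.1, HTSeq without a version and TAIR10 are named per the submitters' processing notes, without the part each played. A needle contig carries an Arabidopsis locus in 34273 cases (57.9%), which name 10739 distinct loci. The Gene Ontology field contains unescaped tabs, so that 29654 lines are longer than the 80 header cells (up to 145). The counts were therefore read as the last 75 cells of each line and matched to the last 75 header names. For 28 columns the unit recorded for the deposited file is other, because a reader counting cells from the left finds Gene Ontology terms there, and read from the right they are counts like the rest. No value is 0. The most frequent low value is 2 in 72 libraries and 4 in 3 libraries, and 4.6% of all values are 1 to 2. The lowest values were therefore read as a floor of unstated origin. The main comparisons used them unchanged as counts, and a later alternative set them to 0. These 3 libraries are all of Salmon Arm, tree 14 at Wiesloch in July and trees 14 and 13 at Schluchsee in September. Total counts ran from 18.54 to 47.51 M per library (median 34.05 M, where M is 10 to the power of 6). No contig held more than 0.673% of the summed counts of all libraries. Several contigs often match the same locus, and the authors' counting could split reads between them, so values of single contigs are uncertain where near-identical contigs exist.

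Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalisation (factors 0.897 to 1.11) and the quasi-likelihood test, with Benjamini-Hochberg adjustment over all contigs tested and a threshold of 0.05. Adjusted p-values of single contigs below are from this test unless another tool is named. An SE of a log2 fold change is its size divided by the square root of the F statistic of this test. Month comparisons used all 75 libraries and 16 group means, averaged with equal weight over the 4 combinations of provenance and site (59177 contigs tested, 12 removed by the filter, prior degrees of freedom 2.92). Such a log2 fold change averages 4 log ratios and can differ from the ratio of mean CPM (counts per M counts of the library). Whether the seasonal course differed between sites or provenances was tested with an F test of 3 contrasts in the same model. Provenance and site over all months, and their interaction, were tested on the summed counts of the 25 trees, with the share of each tree's counts from June, July and September as covariates (59186 contigs tested). Within a month, the libraries of that month were fitted with provenance and site as factors (56074 contigs in May, 56547 in June, 56859 in July and 55572 in September). Differences are given as the later minus the earlier month, Cameron Lake minus Salmon Arm, or Schluchsee minus Wiesloch. CPM means use TMM-scaled library sizes.

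Lists of Arabidopsis loci for 20 processes were matched to the contigs, the contig with the highest mean count standing for each locus. The lists and their measured members are light harvesting and photosystems (33 of 42), Calvin cycle (15 of 18), photoprotection (21 of 23), heat shock proteins and chaperones (21 of 23), cold acclimation (10 of 24), abscisic acid and drought (21 of 31), circadian clock and photoperiod (16 of 25), phenylpropanoid and lignin (14 of 15), flavonoid (8 of 10), terpenoid backbone (17 of 20), starch and sugar (12 of 16), defence and jasmonate (12 of 19), senescence and chlorophyll breakdown (7 of 12), wax and cuticle (4 of 6), cytosolic ribosomal proteins (8 of 12), xylem and secondary wall (4 of 8), dividing cells and meristem (6 of 12), guard cells (2 of 5), plastid-encoded transcripts (11 of 11) and mitochondrion-encoded transcripts (3 of 3). Camera (limma 3.58.1) tested each list against all other contigs on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Fry tested, without comparing with other genes, whether members moved on balance one way or in either direction.

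Named contigs follow a rule: in each month comparison and for provenance and site, among contigs past the threshold with a mean of at least 5 CPM and a locus, the 8 with the largest rise and the 8 with the largest fall, and from each list up to 2 rising and 2 falling members with the smallest adjusted p. Members of a list that did not pass could be named too. Contigs outside the rule are given as such. Comparisons, lists, this rule and the alternatives were chosen before the data were examined, apart from those stated to be later.

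Whether equal replicate numbers in different months meant 1 tree was checked by correlating libraries from different months after the group means of log2 CPM were taken off. Libraries given the same tree had a median r of 0.655 (89 pairs, 85 above 0.1), and libraries of different trees of the same provenance and site one of -0.121 (437 pairs, 33 above 0.1), r here being across genes, which are not independent replicates. The consensus correlation within a tree was 0.438.

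The tests were tried on counts simulated from the contigs' mean levels, dispersions and library sizes, with 200 contigs changed. Contigs and libraries were drawn independently, without a tree effect. These runs therefore do not test how the month and block fits handle repeated trees. The changed contigs were drawn from those above a minimum expected count, so the recoveries leave out weak contigs. With 100 contigs changed 2-fold and 100 changed 4-fold, the quasi-likelihood test recovered 78 and 97 in June minus May (59177 contigs, 8 false among 183 calls) and 74 and 97 in July minus June (2 among 173). It recovered 51 and 88 for provenance on tree sums (59186 contigs, 4 among 143), and 36 and 84 for month by site (59174 contigs, 10 among 130). Within a month the site comparison recovered 46 and 86 in May (55692 contigs, 4 among 136), 27 and 81 in June (56200, 3 among 111), 41 and 80 in July (56607, 6 among 127) and 40 and 81 in September (55135, 3 among 124). DESeq2 recovered 82 and 97 (June minus May, 7998 contigs, 14 among 193), edgeR with the tree as block 74 and 93 (8000 contigs, 7 among 174), and limma-voom with the tree as random block 91 and 95 (provenance, 7999 contigs, 12 among 198). False calls were above 5% for month by site (7.7%), DESeq2 (7.3%) and limma-voom (6.1%). Where nothing was changed, 0 contigs were called by edgeR. With the 15 Calvin cycle members raised 1.5-fold, camera called that list alone out of 20 (adjusted p = 8.4e-64). Since the simulated contigs were independent of each other, this run does not test the preset inter-gene correlation on which the list calls rest.

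The alternatives chosen beforehand were DESeq2 1.42.0, RLE size factors, no low-count filter, the tree as a replicate block, limma-voom with the tree as a random block, no month shares, clock time as a covariate, leaving out each tree in turn, and for lists an estimated correlation, fry and counts summed per locus. Added after the data were seen were the lowest values set to 0, the 3 libraries with a most frequent low value of 4 left out, the plastid transcript level as a covariate, the tree as a block in the list tests, and the list tests without 1 tree. Chance was tested by refitting other splits of the samples: 60 or 40 draws for the month comparisons, 80 for tree sums and 100 otherwise. These refits took the negative binomial dispersion trend from the real fit and estimated the quasi-likelihood dispersions again. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Nothing was left out of the comparisons, and no reference sequence was used.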

Results

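The needle transcriptome of Douglas-fir was compared between months, growing sites and provenances. Salmon Arm lies in the interior and Cameron Lake near the coast of British Columbia, and Wiesloch is a lowland and Schluchsee a mountain site in south-west Germany. The first 3 principal components of the 75 libraries held 12.4%, 10.5% and 6.6% of the variance. Provenance accounted for 27% and site for 24.9% of the first component, provenance for 37.2% of the second, and month for 74% of the third.

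Heat shock transcripts rose between May and June. HSP90.1, a cytosolic chaperone, rose from 31 ± 36.9 CPM in May (SD, n = 20 libraries) to 195 ± 147 CPM in June (n = 17). Its log2 fold change was 2.57 (SE 0.23, adjusted p = 2.7e-13). HSP101, a chaperone that dissolves protein aggregates, rose from 42.3 ± 17.1 to 132 ± 67.7 CPM (1.57, SE 0.14, adjusted p = 1.8e-13). CCA1, a clock gene that peaks in the morning, fell from 134 ± 32.5 to 50.8 ± 21.9 CPM (-1.43, SE 0.14, adjusted p = 8.4e-12). TOC1, a clock gene of the evening, rose from 7.12 ± 1.93 CPM in May by a log2 fold change of 1.13 (SE 0.10, adjusted p = 7.2e-13).

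In all, 11257 of 59177 contigs, with 3685 loci, changed between May and June. Of these 5662 rose, 5595 fell and 2023 changed at least 2-fold. Of the 21 measured heat shock proteins and chaperones 17 rose, none fell and 4 did not pass, with 20 rising adjusted over the list alone. Their median log2 fold change was 1.02 (camera adjusted p = 3.6e-17). One May library, Salmon Arm tree 14 at Wiesloch, stood apart from its group in this list, with a mean of 4.65 log2 CPM beside 3.13 to 3.38 in the others. A small heat shock protein contig of AT5G51440 rose from 1.77 ± 4.71 to 16.1 ± 14.8 CPM (3.73, SE 0.35, adjusted p = 1.2e-12). Phytoene synthase (PSY), of carotenoid synthesis, fell from 185 ± 44.3 to 107 ± 17.5 CPM (-0.77, SE 0.09, adjusted p = 2.3e-10). Granule-bound starch synthase (GBSS1) fell from 2160 ± 647 to 1170 ± 400 CPM (-0.93, SE 0.14, adjusted p = 5.9e-07). Of 12 starch and sugar genes 5 fell, 1 rose and 6 did not pass, the same counts as adjusted over the list alone. Their median of -0.31 passed (adjusted p = 0.024, but adjusted p = 0.64 with an estimated correlation and 0.078 with counts summed per locus). Of 17 terpenoid backbone genes 4 fell, none rose and 13 did not pass, with 4 falling adjusted over the list alone. Their median was also -0.31 (adjusted p = 0.03, but adjusted p = 0.4 with an estimated correlation and 0.21 with counts summed per locus). Of 11 plastid-encoded transcripts 8 fell and 3 did not pass, with 11 falling adjusted over the list alone (median -0.96, adjusted p = 0.0021, but adjusted p = 0.66 with an estimated correlation). In May 4 Salmon Arm libraries had the highest means of this list, tree 12 at Wiesloch (7.41 log2 CPM) and trees 12, 16 and 13 at Schluchsee (7.5, 7.13 and 7.03), and the other 16 lay at 4.18 to 6.04.

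The other lists did not pass between May and June. Adjusted p was 0.14 for light harvesting and photosystem genes (2 rose, 1 fell, 30 did not pass) and for Calvin cycle genes (3 rose, 12 did not pass). It was also 0.14 for abscisic acid and drought genes (6 rose, 4 fell, 11 did not pass) and for circadian clock and photoperiod genes (8 rose, 2 fell, 6 did not pass). Adjusted over the list alone, 7 abscisic acid genes rose and 4 fell, 9 clock genes rose and 4 fell, and 3 cold acclimation genes rose and 4 fell. Phenylpropanoid and lignin genes (1 rose, 1 fell, 12 did not pass) had the same adjusted p of 0.14. Flavonoid genes (2 rose, 3 fell, 3 did not pass) had 0.59, and defence and jasmonate genes (2 rose, 10 did not pass) had 0.65. Photoprotection genes (2 rose, 2 fell, 17 did not pass) had 0.73, and none of 8 cytosolic ribosomal proteins passed (0.77). Senescence and chlorophyll breakdown genes (1 fell, 6 did not pass) had 0.69, and wax and cuticle genes (1 fell, 3 did not pass) had 0.67. None of 3 mitochondrion-encoded transcripts passed (0.37), with 2 falling adjusted over the list alone. Among lists of other cell types, xylem and secondary wall genes (1 rose, 3 did not pass) had 0.59. Dividing cell and meristem genes (1 rose, 5 did not pass) had 0.88, and neither of the guard cell genes passed (0.72). The cold acclimation list (2 rose, 2 fell, 6 did not pass, adjusted p = 0.72) had a negative median (-0.29) and test direction but a positive mean (0.1).

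Within sites, 4598 contigs changed between May and June at Wiesloch and 8315 at Schluchsee. Both sites shared 1966 of these, where independent lists would share 646, and 1941 changed the same way. With the tree as a replicate block 18792 contigs passed, and with clock time as a covariate, on 62 libraries, 5232. HSP90.1, HSP101, CCA1, TOC1, PSY and GBSS1 passed in each of these fits and in every fit that left out 1 tree. With the clock covariate 18 of 58 named contigs did not pass, among them the flowering-time gene FT.

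**Figure D1:**
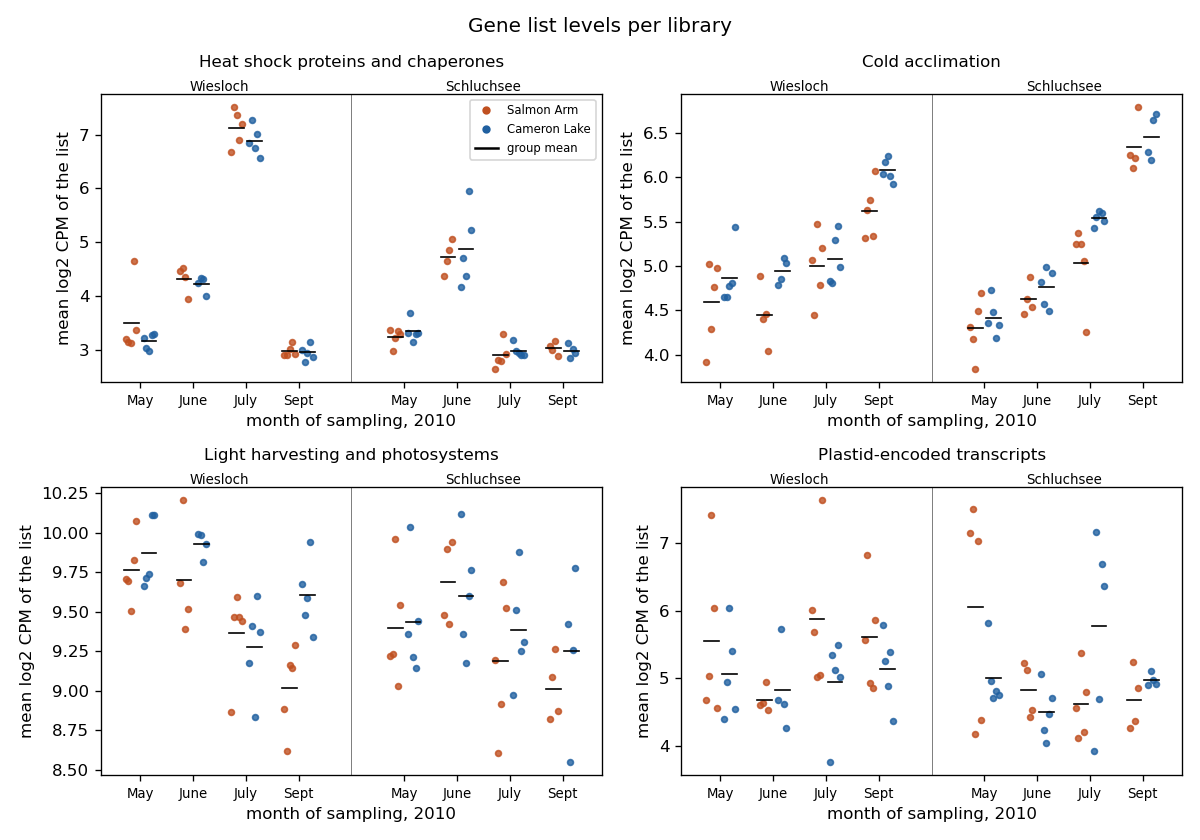
Mean log2 CPM of 4 gene lists per library (points) by month, site and provenance, with group means. The heat shock list was highest in July at Wiesloch, and the cold acclimation list was highest in September at Schluchsee.

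Of 33 light harvesting and photosystem genes 18 fell between June and July and 15 did not pass. The list passed, but with adjusted p = 0.14 with an estimated correlation. LHCB4.2, an antenna protein of photosystem II, fell from 3470 ± 543 CPM in June (SD, n = 17) to 2330 ± 529 CPM in July (n = 20), by a log2 fold change of -0.58 (SE 0.09, adjusted p = 5.6e-06). Rubisco activase (RCA) fell from 4470 ± 851 to 3330 ± 722 CPM (-0.42, SE 0.09, adjusted p = 0.00043). COR47, a dehydrin of cold and drought responses, rose from 8.05 ± 2.67 to 32.5 ± 26.4 CPM (1.58, SE 0.20, adjusted p = 4.4e-08). This averages both sites, and COR47 was higher at Schluchsee in July but did not pass between sites in June. A contig of adenylylsulfate reductase (AT4G21990), which reduces sulfate, fell from 248 ± 129 to 66.6 ± 60.8 CPM (-2.34, SE 0.24, adjusted p = 1.5e-10).

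Altogether 7706 contigs with 2678 loci changed between June and July. Of these 3568 rose, 4138 fell and 1322 changed at least 2-fold. None of the 33 light harvesting and photosystem genes rose, and 24 fell adjusted over the list alone (median -0.43, adjusted p = 4.7e-17, but adjusted p = 0.14 with an estimated correlation). Of 15 Calvin cycle genes 5 fell and 10 did not pass, with 7 falling adjusted over the list alone (median -0.24, adjusted p = 3.4e-05, but adjusted p = 0.32 with an estimated correlation). Heat shock genes rose in 8 cases and 13 did not pass, with 9 rising adjusted over the list alone (median 0.34, adjusted p = 2.3e-05, but adjusted p = 0.14 with an estimated correlation). Cold acclimation genes rose in 2 cases and 8 did not pass, with 3 rising adjusted over the list alone (median 0.38, adjusted p = 0.0028). None of 8 cytosolic ribosomal proteins passed, also adjusted over the list alone, although the list did (median 0.21, adjusted p = 0.029). This call ended with the tree as a block (0.14), with counts summed per locus (0.1) and at adjusted p = 0.52 with an estimated correlation. Plastid-encoded transcripts rose in 6 cases, fell in 1 and did not pass in 4, with 10 rising and 1 falling adjusted over the list alone. Their median was 0.75 (adjusted p = 0.011, but adjusted p = 0.65 with an estimated correlation).

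The sites took different courses from June to July. At Wiesloch 14862 contigs changed and at Schluchsee 10086. Both shared 4248, where independent lists would share 2533, and 833 of those changed the same way. At Wiesloch the contig of HSP90.1, GAEK01023193.1, had 113 ± 41.5 CPM in June and 1580 ± 383 CPM in July in Salmon Arm (n = 4 and 5), and 96.4 ± 24.8 and 1310 ± 214 CPM in Cameron Lake (n = 4 and 5). At Schluchsee it had 234 ± 91.3 and 13.9 ± 5.53 CPM in Salmon Arm (n = 4 and 5), and 310 ± 210 and 13.1 ± 7.1 CPM in Cameron Lake (n = 5 each). The heat shock list rose by a median log2 of 2.49 at Wiesloch and fell by 1.8 at Schluchsee. The adjusted p of this difference was 1.1e-30, and 9.4e-06 with an estimated correlation. With the tree as a replicate block 12937 contigs changed over both sites, and with clock time as a covariate 3058. With that covariate 18 of the 44 named contigs did not pass, while LHCB4.2, RCA, COR47 and the AT4G21990 contig isotig38219 did.

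The cold and heat lists moved apart between July and September. A contig of AT3G05880, a small hydrophobic peptide induced by stress, rose from 2.07 ± 2.65 CPM in July (SD, n = 20) to 76.5 ± 60.3 CPM in September (n = 18). Its log2 fold change was 7.02 (SE 0.27, adjusted p = 3.6e-30). In 11 of the 20 July libraries this contig lay above the lowest values, so the size of the change is less certain than the SE shows. COR47 rose from 32.5 ± 26.4 to 204 ± 174 CPM (2.7, SE 0.20, adjusted p = 2e-17). FT, which promotes flowering in Arabidopsis, rose from 21.2 ± 21.4 to 117 ± 40.1 CPM (3.34, SE 0.27, adjusted p = 1.3e-15). HSP90.1 fell from 729 ± 768 to 11.3 ± 3.82 CPM (-3.63, SE 0.25, adjusted p = 4.6e-19).

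September differed from July in 19151 contigs with 5300 loci, of which 9055 rose, 10096 fell and 4583 changed at least 2-fold. Of 21 heat shock genes 20 fell, none rose and 1 did not pass, also adjusted over the list alone (median -2.18, adjusted p = 7.2e-24). HSFA2, a heat shock transcription factor, fell from 238 ± 186 to 28 ± 10 CPM (-2.49, SE 0.15, adjusted p = 1.7e-20). Cold acclimation genes rose in 6 cases, fell in 2 and did not pass in 2, also adjusted over the list alone (median 0.82, adjusted p = 6.4e-05). The clock gene LUX fell from 131 ± 68.5 to 34.4 ± 10.1 CPM (-1.87, SE 0.14, adjusted p = 3.2e-17). Allene oxide synthase (AOS), an enzyme of jasmonate synthesis, fell from 199 ± 70.7 to 64.3 ± 18.6 CPM (-1.58, SE 0.16, adjusted p = 1.9e-12). The defence and jasmonate list (3 fell, 9 did not pass, also adjusted over the list alone) had an adjusted p of 0.055. It passed with the tree as a block (0.024) or counts summed per locus (0.034). Photoprotection genes rose in 9 cases, fell in 1 and did not pass in 11, also adjusted over the list alone. Their median was 0.27 (adjusted p = 0.0067, but adjusted p = 0.41 with an estimated correlation and 0.14 with counts summed per locus). Cytosolic ribosomal proteins rose in 5 cases and did not pass in 3, also adjusted over the list alone (median 0.39, adjusted p = 0.0067, but adjusted p = 0.41 with an estimated correlation).

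At Wiesloch 24833 contigs changed between July and September and at Schluchsee 4541. Both shared 2657, where independent lists would share 1906, and 1996 of those changed the same way. The heat shock list fell at Wiesloch (median -4.13) and had a median of 0.11 at Schluchsee. This difference had an adjusted p of 5.2e-30, or 9.4e-06 with an estimated correlation. Contigs that rose from May to June and then fell from July to September numbered 2562, where independent lists would share 966. Another 2170 fell and then rose, where independent lists would share 856. The contig of FT, GAEK01018727.1, had means of 3.43 ± 2.82 and 3.33 ± 0.782 CPM at Wiesloch in July (Salmon Arm and Cameron Lake, n = 5 each). At Schluchsee it had 44.9 ± 21.6 and 33.3 ± 5.64 CPM in that month (n = 5 each). In the month comparisons 4 list calls held with an estimated correlation. These were heat shock between May and June (0.00074) and between July and September (3.3e-05), and cold acclimation between June and July (0.049) and between July and September (0.0011).

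**Figure D2:**
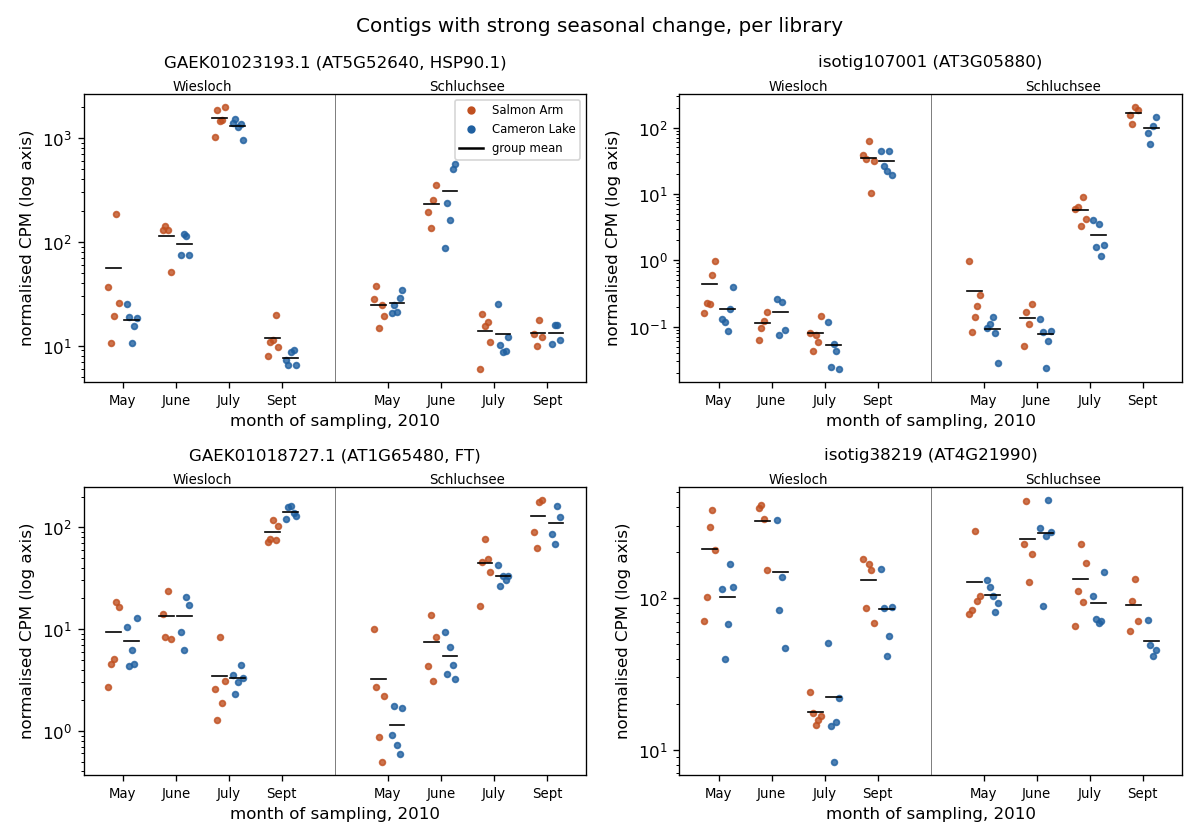
CPM on a log axis of 4 contigs (HSP90.1 GAEK01023193.1, AT3G05880, FT and AT4G21990) per library by month, site and provenance. HSP90.1 reached means of 1580 and 1310 CPM in July at Wiesloch and lay at 13.9 and 13.1 CPM in July at Schluchsee.

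The seasonal course differed between the sites in 20678 of 59177 contigs with 5757 loci, and in 13325 with clock time as a covariate. Among the 193 named contigs 94 passed this test of month by site, beside 34.9% of all contigs. None of them passed that of month by provenance (edgeR). The named contigs were picked from these same data for their changes, which favours the first count. With so few calls over all contigs the second says little about them. Over all contigs month by provenance had 2668 at an unadjusted p under 0.05 and passed for 2 (8 by DESeq2), named here although they were chosen after their values were seen. One was isotig22235, without a locus (adjusted p = 0.036), whose difference, Cameron Lake minus Salmon Arm, was 0.39 in May (adjusted p = 0.18) and -0.96 in July (adjusted p = 0.00019). The other was GAEK01000451.1, annotated as hydrophobic protein LTI6A (AT3G05890, adjusted p = 0.046), with a mean of 0.371 CPM. The count was 0 with the clock covariate and with the plastid level as a covariate (edgeR, 2686 and 2332 at an unadjusted p under 0.05). It was 1 with the lowest values set to 0 and 1 with 3 libraries left out (2307 and 4191 at an unadjusted p under 0.05). With the tree as a replicate block it was 3, with 4754 at an unadjusted p under 0.05. It was 0 without Salmon Arm tree 11 or 12 at Wiesloch or 12, 13, 14 or 16 at Schluchsee, and 1 without Salmon Arm tree 14, 15 or 16 at Wiesloch. For Cameron Lake it was 0 without tree 12, 13 or 15 at Wiesloch or 11, 12, 14, 15 or 16 at Schluchsee, and 1 without tree 9 or 16 at Wiesloch or 9 or 10 at Schluchsee.

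On counts summed over the months of each tree, heat shock transcripts were lower at Schluchsee than at Wiesloch. Such sums are not an average of the months, since a month of high counts, as July at Wiesloch for these genes, weighs more. The month shares allow for a month effect common to both sites, while the seasonal course differed between the sites. How far this affects the site differences was not tested beyond the fit without month shares. Within months the heat shock list was lower at Schluchsee in July and higher in June (but adjusted p = 0.64 with an estimated correlation). It did not pass in May (median -0.08, adjusted p = 0.84) or September (median 0.1, adjusted p = 0.74). HSP70T-2, a chaperone of the HSP70 family, had 58.3 ± 23 CPM at Wiesloch (SD, n = 12 trees) and 20.8 ± 11 CPM at Schluchsee (n = 13). Its log2 difference was -1.57 (SE 0.16, adjusted p = 4.2e-06). COR47, a dehydrin, had 28.3 ± 17.3 CPM at Wiesloch and 99.1 ± 74.8 CPM at Schluchsee (1.95, SE 0.27, adjusted p = 8.5e-05). The clock gene RVE1 was higher at Schluchsee (46.1 ± 10.2 against 21.3 ± 4.33 CPM, 1.12, SE 0.12, adjusted p = 1e-05). Libraries with a time were taken at a mean of 14.23 h at Wiesloch and 13.75 h at Schluchsee. Clock time was not a covariate in the site fit over all months, so for clock genes site and hour were not separated. BAM3, a chloroplast beta-amylase that breaks down starch, was lower at Schluchsee (15.2 ± 7.54 against 59.2 ± 32.1 CPM, -2.12, SE 0.31, adjusted p = 0.00013).

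Over all months 9976 of 59186 contigs, with 3424 loci, differed between the sites, 5077 higher and 4899 lower at Schluchsee. Of 21 heat shock genes 17 were lower at Schluchsee and 4 did not pass, also adjusted over the list alone (median -1.57, adjusted p = 4.6e-16, and 0.021 with an estimated correlation). HSP21, a small chaperone of the chloroplast (contig GAEK01018868.1), had 168 ± 148 CPM at Wiesloch and 14.2 ± 20.1 CPM at Schluchsee (-3.93, SE 0.68, adjusted p = 0.00052). Its named sister contigs GAEK01004310.1, isotig18971 and isotig18972 passed as well, but not with the tree as a random block. CCA1 was higher at Schluchsee (122 ± 24.9 against 69.6 ± 18.4 CPM, 0.83, SE 0.12, adjusted p = 0.0001). As for RVE1, clock time was not a covariate in this fit. Of 33 light harvesting and photosystem genes 3 were lower and 30 did not pass, with 0 adjusted over the list alone (median -0.15, adjusted p = 0.043, but adjusted p = 0.99 with an estimated correlation). Without Salmon Arm tree 9 at Wiesloch this photosystem list did not pass, nor did the plastid-encoded list in September. Of the 47 contigs named for site 35 passed in every fit that left out 1 tree, HSP70T-2, COR47, RVE1, CCA1, BAM3 and GAEK01018868.1 among them. In limma-voom with the tree as a random block 9 of the 47 did not pass, and without month shares 10, none of them among these 6.

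**Figure D3:**
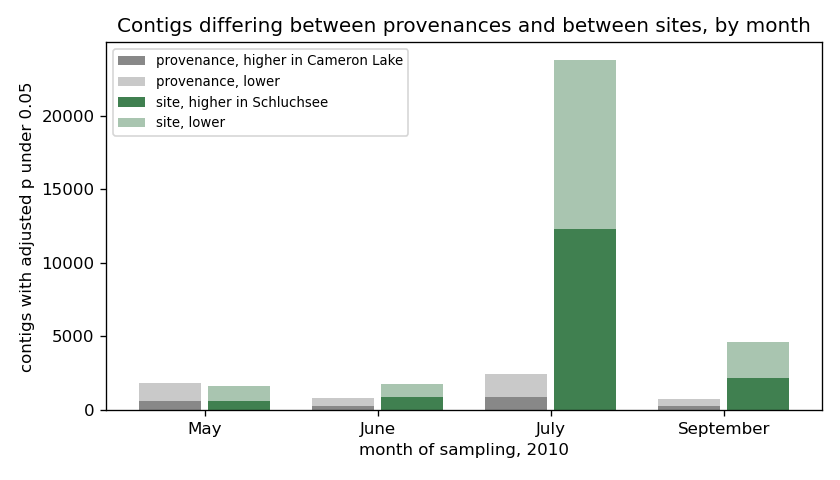
Number of contigs past the threshold in each month (bars, split into higher and lower) for provenance and for site. The site difference was largest in July with 23782 contigs, and the provenance difference had more contigs lower than higher in Cameron Lake in each month.

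The site difference was largest in July. HSP90.1 then had a log2 difference of -6.73 (SE 0.28, adjusted p = 2e-12), HSP101 of -3.79 (SE 0.17, adjusted p = 4.4e-12) and HSFA2 of -2.79 (SE 0.20, adjusted p = 3.4e-09), with 10 libraries per site. In the same month CCA1 (3.39, SE 0.18, adjusted p = 3.2e-11) and FT (3.53, SE 0.31, adjusted p = 3.4e-08) were higher at Schluchsee. FT was lower there in May (-2.14, SE 0.50, adjusted p = 0.026). No contig passed in that month with clock time as a covariate (edgeR, 3223 at an unadjusted p under 0.05), but clock time and site overlapped little then, so that fit says little about this difference. COR47 was higher at Schluchsee in July (2.34, SE 0.31, adjusted p = 5.4e-06) and September (2.51, SE 0.21, adjusted p = 5e-06). It did not pass in May (-0.29, adjusted p = 0.62) or June (adjusted p = 0.99).

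In July 23782 contigs differed between the sites, 12331 higher and 11451 lower at Schluchsee. In May 1668 differed (610 higher, 1058 lower), in June 1774 (888 higher, 886 lower) and in September 4605 (2194 higher, 2411 lower). Across months 63 contigs differed the same way in all 4 (27 higher, 36 lower), and 920 passed in opposite directions in different months. The months share trees and are not independent repeats. In July 19 of 21 heat shock genes were lower at Schluchsee and 2 did not pass, also adjusted over the list alone (median -3.8, adjusted p = 6e-19, and 0.00012 with an estimated correlation). In June 5 of 20 tested heat shock genes were higher there and 15 did not pass, with 7 higher adjusted over the list alone (median 0.54, adjusted p = 0.015, but adjusted p = 0.64 with an estimated correlation). ROF1, a co-chaperone, was among them (0.81, SE 0.14, adjusted p = 0.01). None of 15 Calvin cycle genes passed in June, with 3 lower adjusted over the list alone (median -0.22, adjusted p = 0.0012, but adjusted p = 0.64 with an estimated correlation). Of 12 starch and sugar genes 2 were lower and 10 did not pass in that month, with 1 higher and 4 lower adjusted over the list alone. Their median was -0.28 (adjusted p = 0.019, but adjusted p = 0.64 with an estimated correlation). With counts summed per locus, light harvesting (0.019), photoprotection (0.019) and ribosomal proteins (0.024) also passed in June.

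In May 3 light harvesting and photosystem genes were lower at Schluchsee and 30 did not pass, with 4 lower adjusted over the list alone (median -0.32, adjusted p = 2.9e-07, but adjusted p = 0.86 with an estimated correlation). None of 8 cytosolic ribosomal proteins passed in May, with 3 lower adjusted over the list alone (median -0.41, adjusted p = 0.016, but adjusted p = 0.86 with an estimated correlation). In September cold acclimation genes were higher in 3 cases, lower in 1 and not past in 6, also adjusted over the list alone. Their median was 0.36 (adjusted p = 0.047, but adjusted p = 0.57 with an estimated correlation and 0.13 with counts summed per locus). Calvin cycle genes were lower in 2 cases and not past in 13, also adjusted over the list alone (median -0.24, adjusted p = 0.012, but adjusted p = 0.88 with an estimated correlation). Plastid-encoded transcripts were lower in 2 cases and not past in 9, with 5 lower adjusted over the list alone. Their median was -0.71 (adjusted p = 0.047, but adjusted p = 0.88 with an estimated correlation and 0.075 with counts summed per locus).

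The site counts of May, June and September moved with the method. DESeq2 gave 4085 contigs in May, 5275 in June and 7467 in September. With clock time as a covariate 0 contigs passed in May (edgeR, 3223 at an unadjusted p under 0.05) and 31 in June, of which 2 were higher. These 2 fits could hardly tell site from clock time. In May the 9 Wiesloch libraries with a time were taken at 14.17 to 15.33 h and the 6 at Schluchsee at 13.22 to 14.37 h, and in June 3 Wiesloch libraries had a time. The plastid level as a covariate gave 1031 in June and 2602 in September. In September 2880 passed without Salmon Arm trees 14 and 13 at Schluchsee, the libraries of that month with a most frequent low value of 4. In May the count was 1098 without Salmon Arm tree 15 at Wiesloch, and 1058 and 1109 without Salmon Arm trees 12 and 13 at Schluchsee. It was 1002 without Cameron Lake tree 13 at Wiesloch, and 923 and 996 without Cameron Lake trees 14 and 10 at Schluchsee. In June it was 834, 1057 and 985 without Salmon Arm trees 9, 15 and 13 at Wiesloch, and 845 and 921 without Salmon Arm trees 16 and 13 at Schluchsee. It was 1079, 890 and 1031 without Cameron Lake trees 16, 9 and 15 at Wiesloch, and 960 and 969 without Cameron Lake trees 10 and 11 at Schluchsee.

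The provenances differed in single contigs by large factors. A histone H2B contig (isotig44994, AT3G45980) had 9.02 ± 3.41 CPM in Cameron Lake (SD, n = 12 trees) and 2.12 ± 2.46 CPM in Salmon Arm (n = 13). Its log2 difference was 2.48 (SE 0.32, adjusted p = 0.00012). A DnaJ chaperone contig (isotig29997, AT5G22080) had 0.385 ± 0.545 CPM in Cameron Lake and 10.9 ± 4.84 CPM in Salmon Arm (-4.77, SE 0.59, adjusted p = 5.8e-05). Basic endochitinase (PR3), a defence protein, was lower in Cameron Lake (32 ± 53.3 against 226 ± 262 CPM, -3.05, SE 0.58, adjusted p = 0.0027). Galactinol synthase (GOLS1), which starts raffinose synthesis, was higher there (2420 ± 519 against 1430 ± 670 CPM, 0.86, SE 0.19, adjusted p = 0.0079).

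Over all months 6348 of 59186 contigs, with 2444 loci, differed between provenances, 2733 higher and 3615 lower in Cameron Lake. A contig of AT3G56500 (isotig13796) had 0.659 ± 0.801 CPM in Cameron Lake and 11.2 ± 5.43 CPM in Salmon Arm (-4.13, SE 0.46, adjusted p = 2.3e-05). Of 15 Calvin cycle genes 6 were higher, none lower and 9 not past, with 9 higher adjusted over the list alone (median 0.29, adjusted p = 1.8e-05, but adjusted p = 0.55 with an estimated correlation). Phosphoglycerate kinase (PGK1) had 974 ± 180 CPM in Cameron Lake and 706 ± 104 CPM in Salmon Arm (0.42, SE 0.10, adjusted p = 0.014). Of 16 clock genes 6 were higher and 10 not past, with 7 higher adjusted over the list alone. Their median was 0.13 (adjusted p = 0.041, but adjusted p = 0.55 with an estimated correlation and 0.065 with counts summed per locus). Clock time was not a covariate in this fit, so for clock genes provenance and hour were not separated. Of 33 light harvesting and photosystem genes 4 were higher and 29 not past, also adjusted over the list alone. Their median was 0.1 (adjusted p = 0.041, but adjusted p = 0.72 with an estimated correlation and 0.065 with counts summed per locus). The photoprotection list (median 0.18, mean -0.03) and the starch list (median 0.24, mean -0.05) had a mean of the other sign than the median and the test, and did not pass. Isopentenyl diphosphate isomerase (IPP1), of the terpenoid backbone, was lower in Cameron Lake (36.8 ± 9.46 against 59.4 ± 16 CPM, -0.72, SE 0.14, adjusted p = 0.0031). No provenance list call held with an estimated correlation, and of the site calls those of heat shock over all months and in July did.

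The tree labelled Salmon Arm tree 9 at Wiesloch lay among the Cameron Lake trees. The position of each tree was measured on the 500 contigs that best parted the provenances when that tree was held out, on a scale from 0 at the mean of the other Salmon Arm trees to 1 at that of the Cameron Lake trees. Its median position was 0.88, with the other Salmon Arm trees at -0.08 to 0.15 and the Cameron Lake trees at 0.8 to 1.08. Each of its 4 libraries lay at 0.71 or above. Without it 9074 contigs differed between provenances (4252 higher, 4822 lower), and all 44 contigs named for provenance still passed. Without it the defence and jasmonate list passed as well (2 of 12 lower, adjusted p = 0.023, but adjusted p = 0.33 with an estimated correlation). Without Salmon Arm tree 15 at Wiesloch the count was 3949. DESeq2 gave 10141 contigs (4648 higher, 5493 lower). Limma-voom with the tree as a random block gave 9923, with 4948 higher and 4975 lower and so near balance. Of the 44 named contigs 26 passed in every fit that left out 1 tree, isotig44994, isotig13796, isotig29997, PR3, GOLS1, PGK1 and IPP1 among them. With the tree as a random block 10 of the 44 did not pass, and without month shares also 10, none of them among these 7.

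**Figure D4:**
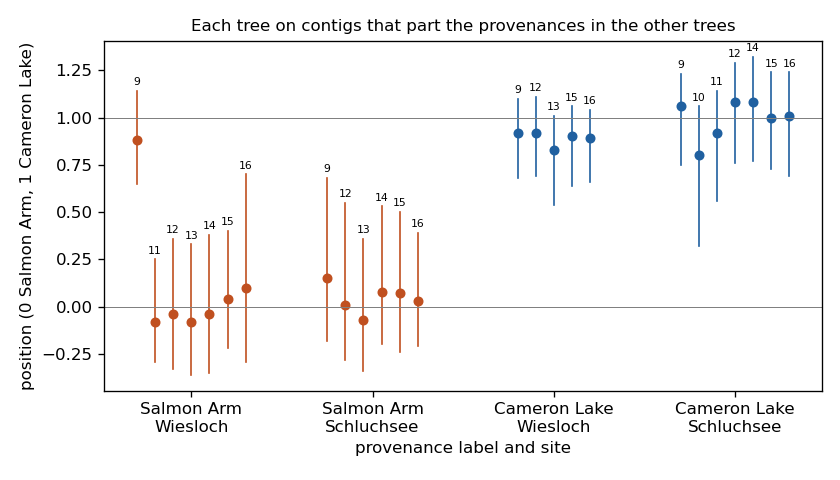
Median position of each tree between the provenances over 500 contigs chosen with that tree held out, where 0 is the mean of the other Salmon Arm trees and 1 that of the Cameron Lake trees. The tree labelled Salmon Arm tree 9 at Wiesloch lies at 0.88, within the range of the Cameron Lake trees.

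Within months the same single contigs parted the provenances. They had been named on the summed counts of these same libraries, so the single months are no independent test of them. The DnaJ contig isotig29997 was lower in Cameron Lake in May (-5.82, SE 0.22, adjusted p = 3.4e-12, n = 10 libraries each) and June (-5.65, SE 0.52, adjusted p = 5.1e-05). It was also lower in July (-3.97, SE 0.82, adjusted p = 0.011) and September (-5.47, SE 0.60, adjusted p = 0.00021). The histone contig isotig44994 was higher in May (1.93, SE 0.37, adjusted p = 0.008), June (2.68, SE 0.40, adjusted p = 0.0024), July (2.17, SE 0.39, adjusted p = 0.0043) and September (2.56, SE 0.42, adjusted p = 0.0056). PR3 did not pass in May (-2.55, SE 0.77, adjusted p = 0.072). It was lower in June (-2.64, SE 0.62, adjusted p = 0.043), July (-4.01, SE 0.55, adjusted p = 0.00035) and September (-3.25, SE 0.70, adjusted p = 0.027).

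The number of contigs that differed between provenances was 1837 in May (596 higher, 1241 lower in Cameron Lake) and 849 in June (250 higher, 599 lower). It was 2425 in July (869 higher, 1556 lower) and 768 in September (252 higher, 516 lower). Of 53977 contigs tested in each month 203 passed the same way in all 4 (24 higher, 179 lower), and none passed in opposite directions. Many trees were sampled in several months, so the months are not independent repeats. Calvin cycle genes had a positive median in each month. It was 0.27 in May (adjusted p = 0.00086, but adjusted p = 0.47 with an estimated correlation) and 0.23 in June (adjusted p = 0.0052, but adjusted p = 0.9 with an estimated correlation). It was 0.27 in July (adjusted p = 0.0023, but adjusted p = 0.72 with an estimated correlation) and 0.33 in September (adjusted p = 3.8e-08, but adjusted p = 0.36 with an estimated correlation). None of the 15 passed in a single month over all contigs (edgeR), while adjusted over the list alone 1 was higher in May, 0 in June, 2 in July and 10 in September. None of 12 defence genes passed in May, with 2 lower adjusted over the list alone (median -0.58, adjusted p = 0.0039, but adjusted p = 0.34 with an estimated correlation). None of 11 plastid-encoded transcripts passed in May, with 9 lower adjusted over the list alone (median -1.32, adjusted p = 0.024, but adjusted p = 0.8 with an estimated correlation). Of 3 mitochondrion-encoded transcripts 2 were lower in May and 1 not past, with 3 lower adjusted over the list alone (median -2.27, adjusted p = 0.0034, but adjusted p = 0.34 with an estimated correlation). The 4 Salmon Arm libraries with the highest plastid means in May, of tree 12 at Wiesloch and trees 12, 16 and 13 at Schluchsee, also had the highest mitochondrial means (2.56 to 3.37 log2 CPM).

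In July 2 clock genes were higher in Cameron Lake and 14 not past, with 5 higher adjusted over the list alone (median 0.17, adjusted p = 0.025, but adjusted p = 0.72 with an estimated correlation). Clock time was not a covariate in this list test, so provenance and hour were not separated for these genes. None of 12 starch and sugar genes passed in July, with 7 higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 0.0073, but adjusted p = 0.72 with an estimated correlation). In September 1 light harvesting and photosystem gene was higher and 32 not past, with 14 higher adjusted over the list alone (median 0.41, adjusted p = 1.3e-11, but adjusted p = 0.38 with an estimated correlation). It was LHCA1 (0.82, SE 0.20, adjusted p = 0.045), chosen after its values were seen. None of 21 photoprotection genes passed in September, with 7 higher and 1 lower adjusted over the list alone (median 0.28, adjusted p = 0.00037, but adjusted p = 0.38 with an estimated correlation). With counts summed per locus the phenylpropanoid list in May (0.037) and the mitochondrial list in September (0.047) also passed. Without Salmon Arm tree 9 at Wiesloch the flavonoid list passed in September (adjusted p = 0.042, but adjusted p = 0.31 with an estimated correlation).

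The provenance counts within months moved with the method and with single trees. DESeq2 gave 4491 contigs in May, 2995 in June, 5942 in July and 2697 in September. With clock time as a covariate 121 passed in May, 20 in June and 463 in September. With the lowest values set to 0, 488 passed in June. In July 1602 passed without Salmon Arm tree 14 at Wiesloch, the library of that month with a most frequent low value of 4. This is the same fit as the one without this tree below. Without Salmon Arm tree 9 at Wiesloch the counts were 3512 in May (1351 higher, 2161 lower), 1894 in June (717 higher, 1177 lower) and 1594 in September (665 higher, 929 lower). In July it was 8561, nearly balanced with 4258 higher and 4303 lower. Without it 470 contigs passed the same way in all 4 months (105 higher, 365 lower) and 1 in opposite directions. In June the count was 555 without Salmon Arm tree 13 and 558 without Cameron Lake tree 9 at Wiesloch, and 535, 520 and 424 without Cameron Lake trees 15, 9 and 14 at Schluchsee. In July it was 1355, 1460 and 1602 without Salmon Arm trees 11, 12 and 14 at Wiesloch, and 1591 without Salmon Arm tree 13 at Schluchsee. It was 1489, 1515 and 1458 in July without Cameron Lake trees 15, 9 and 12 at Schluchsee. In September it was 500 and 510 without Salmon Arm trees 11 and 13 and 461, 510 and 507 without Cameron Lake trees 16, 9 and 12, all at Wiesloch.

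The provenance difference was not shown to depend on the site. For the interaction of provenance and site 0 of 59186 contigs passed (edgeR quasi-likelihood test on 25 trees), with 4293 at an unadjusted p under 0.05. DESeq2 gave 224 contigs and limma-voom with the tree as a random block 44. The edgeR count was 2 without Salmon Arm tree 9 and 4 without tree 15 at Wiesloch, and 1 without Salmon Arm tree 16 at Schluchsee. It was 1 and 2 without Cameron Lake trees 9 and 14 at Schluchsee.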

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

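In this part the tests of counts summed per locus and of shallower Salmon Arm trees were chosen after the result was seen. The check of a site difference equal in all months was not written down beforehand either. The same holds for the shares of contigs lower in Cameron Lake with a Salmon Arm tree left out. The other tests were written down before the result was seen.

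Single libraries stood apart from their group of 4 or 5 in 8 of 80 tests, each of 1 of the 16 groups on depth or 1 of 4 lists. Chance flags about 1 in 20 such tests. The total of Cameron Lake tree 9 at Wiesloch in September was 21.28 M, with the others at 31.3 to 35.07 M. On the mean log2 CPM of heat shock genes, Salmon Arm tree 14 at Wiesloch in May lay at 4.65 (others 3.13 to 3.38) and Cameron Lake tree 11 at Schluchsee in July at 3.18 (others 2.91 to 2.98). On cold acclimation genes, Salmon Arm tree 14 at Schluchsee in July lay at 4.25 (others 5.06 to 5.37) and Cameron Lake tree 13 at Wiesloch in May at 5.44 (others 4.65 to 4.81). On photosystem genes, Salmon Arm tree 9 at Wiesloch in July lay at 8.87 (others 9.44 to 9.6). On plastid-encoded transcripts, Cameron Lake tree 13 at Wiesloch in July lay at 3.78 (others 5.02 to 5.49) and Cameron Lake tree 15 at Schluchsee in May at 5.81 (others 4.71 to 4.96).

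The seasonal course differed between sites in 20678 contigs and between provenances in 2, by an F test of the difference itself. Of the 193 named contigs, picked from these same data for their changes, 94 differed between sites, beside 34.9% of all contigs. The difference of list changes between sites was tested as well, with medians at Schluchsee and then Wiesloch. Between May and June the medians were 1.64 and 0.87 for heat shock genes (adjusted p = 0.044) and 0.16 and 0.02 for photosystem genes (0.046). With an estimated correlation these had adjusted p = 0.86 and 0.98, as the Calvin cycle, starch and ribosomal differences below had 0.86. They were 0.03 and 0.24 for Calvin cycle genes (0.033) and -0.11 and -0.12 for starch genes (0.048). For starch the tested quantity, the median of the differences of its genes, was -0.27, lower at Schluchsee, which the 2 medians do not show. Between June and July heat shock genes had -1.8 and 2.49 (1.1e-30), Calvin cycle genes -0.04 and -0.53 (0.04) and ribosomal proteins 0.52 and -0.06 (0.024). Between July and September heat shock genes had 0.11 and -4.13 (5.2e-30) and Calvin cycle genes 0 and 0.32 (0.048).

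Between provenances, medians are given for Cameron Lake and then Salmon Arm. Plastid-encoded transcripts changed by -0.48 and -1.62 between May and June (adjusted p = 0.011) and mitochondrion-encoded ones by 0.12 and -2.07 (0.0014). Starch genes had 0.19 and 0.03 between June and July (0.048). Between July and September photosystem genes had 0.25 and -0.24 (1.7e-05), photoprotection genes 0.52 and 0.05 (0.024) and terpenoid genes 0.14 and -0.12 (0.046). Of these 15 list differences, those of heat shock between June and July and between July and September held with an estimated correlation (9.4e-06 each), and the others had adjusted p = 0.39 to 0.98.

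Other splits of the samples were refitted to see whether chance gives as many contigs. The smallest possible share was 1 of 40 to 1 of 100, and shares were not adjusted over the comparisons, so chance can be made unlikely but not excluded. In the month splits the months of a tree were exchanged within trees sampled in both months and shuffled within provenance and site elsewhere. Chance was unlikely for June minus May (11257 contigs against at most 2587 in another split, 1 of 60 as large), July minus June (7706 against 194, 1 of 60) and September minus July (19151 against 4010, 1 of 60). When months were shuffled without regard to trees the highest others were 2766, 134 and 2411 (40 splits each). Chance was also unlikely for month by site (20678 against 1436, 1 of 100). For month by provenance the share was under 0.05 (2 of 100 splits as large as the real 2 contigs), but another split gave 3 contigs. That count was 0 or 1 in 21 of 25 fits without 1 tree and 0 with clock time or the plastid level as a covariate (edgeR, 2686 and 2332 at an unadjusted p under 0.05). It was 3 with the tree as a replicate block (4754 at an unadjusted p under 0.05, against 2668 without the block) and 8 by DESeq2, so whether the seasonal course differed between provenances stays open. With whole trees moved, provenance (6348 against 1) and site (9976 against 253) each stood alone as 1 of 80. The interaction of provenance and site, with 0 contigs (edgeR, 4293 at an unadjusted p under 0.05, 224 by DESeq2), was matched by all 80 splits, as a count of 0 must be, and the highest of them gave 12.

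Within months, chance was unlikely for provenance in May (1837 against 5), June (849 against 11) and July (2425 against 1124). It was unlikely too for site in May (1668 against 8), June (1774 against 16), July (23782 against 4) and September (4605 against 469). Each real count there was 1 of 100. For provenance in July this is less firm, since single trees moved the count from 1355 (without Salmon Arm tree 11 at Wiesloch) to 8561 (without Salmon Arm tree 9 at Wiesloch). For provenance in September the share was under 0.05 too (768 contigs, 2 of 100 as large), but another split gave 823. Single trees moved that count from 461 (without Cameron Lake tree 16 at Wiesloch) to 1594 (without Salmon Arm tree 9 at Wiesloch), so chance is less firmly argued against there.

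Heat shock transcripts were lower at Schluchsee than at Wiesloch in July, with a median log2 difference of -3.8 (quartiles -7.24 and -1.54, below 0 in 21 of 21 genes). Library quality read as the plastid level was argued against, since with that level as a covariate the median was -3.8 (-7.26 and -1.55). Clock time was argued against by a median of -3.73 (-7.3 and -1.56), and reads shared between near-identical contigs by -3.95 (-7.09 and -2.56, 20 of 21 below 0) with counts summed per locus. A site difference equal in all months is argued against, since the difference of this list changed by a median of -4.41 from June to July and 3.96 from July to September. Camera gave adjusted p = 1.1e-30 and 5.2e-30, and 9.4e-06 each with an estimated correlation. The weather of the sampling day and a site climate that acts in part of the season remain open and untested, since each site was visited on its own day. A warm day at Wiesloch may be a candidate cause, and no value here tells it from such a seasonal difference.

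More contigs were lower than higher in Cameron Lake (56.9%, 95% interval 55.7 to 58.2, of 6348), though with the tree as a random block in limma-voom the sides were near equal (4948 higher, 4975 lower). Contigs with few reads are a candidate explanation: among contigs with a mean of at least 5 CPM 44.4% were lower (42.4 to 46.3), and among the others 65.8% (64.3 to 67.3). Without Salmon Arm tree 9 at Wiesloch these were 44.3% and 59.6%, and 53.1% over all. For sequence variants against the reference contigs, loci with 2 or more called contigs went both ways in 22.3% of cases for provenance (182 of 815) and 12.1% for site (184 of 1524, Fisher's exact p = 1.9e-10). This excess was under the 2 times set beforehand, so a variant and a difference in expression cannot be told apart for these loci, and a real difference between the provenances stays open, untested.

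The tree labelled Salmon Arm tree 9 at Wiesloch lay at 0.88 between the provenances, and without it 9074 contigs differed. A wrong provenance label could give this, and the bound of 0.8 was set beforehand. With each tree held out in turn no Cameron Lake tree lay under 0.8, so a swap between the 2 groups had no partner among these trees, and a single wrong label or a swap with an outside tree needs none. A shallow library set was tested by its lowest total, 22.39 M, which fell between the bounds set beforehand (the lowest of the other trees, 18.54 M, and their median of 24.71 M), so that this test alone could not decide. Low depth was argued against by the 2 Salmon Arm trees with a shallower library, which lay at 0.01 at most, while mixed descent of this tree stays open, untested.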

How the results depend on the processing

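No list call reversed, and of the contigs named for the month comparisons and for provenance and site over all months none that passed reversed. The contigs named within single months were not followed one by one. The larger side of a count turned where both were close. June minus May had 5541 rising and 5718 falling contigs without the filter, and site in July 12050 higher and 12321 lower with the plastid level as a covariate. For site over all months fewer were higher with that covariate (49.3%), without month shares (48.6%) and with 3 libraries left out (49.4%). For site in June this was so with that covariate (43.3%), clock time (6.45%), no filter (48.8%), the lowest values set to 0 (49%) and Salmon Arm tree 9 at Wiesloch left out (335 higher, 499 lower). For site in September more were higher by DESeq2 (50.3%) and with clock time (50.4%). Counts within 1.5 times the reported one are called the same here. RLE size factors, no low-count filter and no month shares moved no count past that bound. Where a value moved, the cause was not tested, except that the clock fits hold 62 of the 75 libraries.

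DESeq2 moved month by provenance to 8 contigs, provenance to 10141 and the interaction to 224. Within months it gave 4491, 2995, 5942 and 2697 for provenance (May to September) and 4085, 5275 and 7467 for site in May, June and September. Limma-voom with the tree as a random block gave 9923 for provenance (4948 higher, 4975 lower) and 44 for the interaction. The tree as a replicate block gave 18792 for June minus May and 12937 for July minus June. Clock time as a covariate gave 5232 for June minus May, 3058 for July minus June, 13325 for month by site and 0 for month by provenance (edgeR, 2686 at an unadjusted p under 0.05). It gave 121, 20 and 463 for provenance in May, June and September, and 0 and 31 for site in May (3223 at an unadjusted p under 0.05) and June, where clock time nearly parts the sites (May) or 3 Wiesloch libraries have a time (June).

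Other alternatives were added after the data were seen. Setting the lowest values to 0 gave 1 for month by provenance and 488 for provenance in June. Leaving out the 3 libraries with a most frequent low value of 4 gave 1 for month by provenance, 1602 for provenance in July and 2880 for site in September. Within July this took out Salmon Arm tree 14 at Wiesloch alone, and within September Salmon Arm trees 14 and 13 at Schluchsee. The plastid level as a covariate gave 0 for month by provenance (2332 at an unadjusted p under 0.05), 1031 for site in June and 2602 for site in September. The 39 list calls were 6 with an estimated correlation, 40 by fry, 77 by fry in either direction and 37 with counts summed per locus. Of 260 list tests these lost 33, 16, 17 and 8 calls and gained 0, 17, 55 and 6. Added later too, the tree as a block ended the call of ribosomal proteins between June and July (0.14), brought in defence between July and September (0.024) and changed no other call. Without Salmon Arm tree 9 at Wiesloch 25 lists passed for provenance and site, as many as with it.

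Leaving out each tree in turn gave 9817 to 11944 contigs for June minus May, 6645 to 7838 for July minus June, 17386 to 19124 for September minus July and 18462 to 21247 for month by site, all the same. Site over all months ran from 8032 to 10286, and in July and September from 22312 to 24365 and 3554 to 4986. Month by provenance ran from 0 to 3 and the interaction from 0 to 4 (highest without Salmon Arm tree 15 at Wiesloch). Provenance ran from 3949 without that tree to 9074 without Salmon Arm tree 9 at Wiesloch. The latter also gave the highest provenance count in May (1254 to 3512), June (424 to 1894), July (1355 to 8561) and September (461 to 1594), and the lowest for site in June (834 to 2479). Site in May ran from 923 to 2031. The lowest counts of provenance in May and June and of site in May were without Cameron Lake tree 14 at Schluchsee, and those of provenance in July and September without Salmon Arm tree 11 and Cameron Lake tree 16 at Wiesloch. The report names each further tree that moved a count by more than 1.5 times.

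Of the named contigs 52 of 58 passed in every such fit for June minus May, 37 of 44 for July minus June, 61 of 67 for September minus July, 26 of 44 for provenance and 35 of 47 for site. With clock time as a covariate 18 of 58, 18 of 44 and 3 of 67 were lost in the month comparisons. Depth limits what can be seen of weak contigs, since values of 1 to 2 lie at the floor, and 4-fold changes were recovered more often than 2-fold ones in simulated data.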

Other observations

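Here the Gene Ontology terms and the correlation of plastid with mitochondrial transcripts were chosen after the data were seen.

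Gene Ontology terms of heat and light stress moved with the heat shock list. Between May and June 134 of 480 contigs of response to heat rose and 27 fell (adjusted p = 7.9e-06, and 0.016 with an estimated correlation), and 165 of 389 of response to hydrogen peroxide rose and 24 fell (5.2e-14, and 0.013). Of 480 contigs of response to high light 167 rose and 27 fell (1.2e-10, and 0.015), and of 645 of protein folding 205 rose and 31 fell (4.2e-09, and 0.021). Between July and September 203 contigs of response to hydrogen peroxide fell and 35 rose (8.1e-17, and 0.0039). In the same interval 211 of response to high light fell and 52 rose (9.5e-11, and 0.012), and 261 of protein folding fell and 84 rose (1.7e-07, and 0.047). In July 217 of 384 contigs of response to hydrogen peroxide were lower at Schluchsee and 38 higher (5e-18, and 0.026). The terms share contigs and many contigs share a locus.

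Translation contigs rose between July and September, 196 of 633, and 12 fell (adjusted p = 6e-08, but adjusted p = 0.41 with an estimated correlation). Of 890 contigs of response to cold 226 rose and 118 fell (0.012, but adjusted p = 0.084 with an estimated correlation), and of 1438 of response to salt stress 381 rose and 191 fell (0.012, but adjusted p = 0.16 with an estimated correlation). Over all months 30 of 266 contigs of defense response were higher at Schluchsee and 3 lower (0.034, but adjusted p = 0.19 with an estimated correlation). Of 168 contigs of photosynthesis 24 were higher and 4 lower in Cameron Lake (0.0089, but adjusted p = 0.76 with an estimated correlation).

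Plastid-encoded transcripts varied between libraries of a group together with mitochondrion-encoded ones. Over 75 libraries, with group means taken off, Pearson's r was 0.87 (Spearman's rho 0.8, permutation p = 1e-05 for each, the smallest the permutations can give, BH-adjusted p = 2e-05 over 2 relations, r = 0.85 without the 2 farthest libraries). Organelle RNA carried over to a varying extent in library preparation could give this. Depth was argued against, with an r of -0.07 between log2 total count and the plastid level (rho -0.08, permutation p = 0.6 and 0.53, BH-adjusted p = 0.6, r = -0.16 without the 2 farthest). A change of organelle transcripts within the needles remains open, untested.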
